A study of Mus musculus with 6 samples.

How the data were processed

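Single cells of whole mouse lung were profiled in 6 libraries, 2 in each of 3 groups, with the 10x Chromium 3′ chemistry. Each deposited matrix gives UMI counts per gene and barcode, one matrix per library, as written by the authors' run of Cell Ranger 3.0.2 on mm10. The values are raw counts with no normalization, and the barcodes are those the program had called as cells. The annotation release is not stated in the labels. Each matrix listed 31056 features, among them an added IRESGFP sequence. UMIs per library totalled 77186469, 98262756, 80567764, 52635472, 43487126 and 70153597 for libraries 1 to 6, from 12324, 16471, 13136, 10351, 8257 and 9941 barcodes.

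Barcodes with fewer than 500 UMIs, fewer than 300 genes or more than 15% mitochondrial UMIs were left out. Doublets were scored per library with Scrublet in scanpy 1.11.5 at an expected rate of 0.8% per 1000 cells, and 1652 were left out, which kept 65218 cells. The score called 1.64 to 3.17% of barcodes per library against an expected 6.61 to 13.18%. Counts were scaled and log-transformed. The 2000 most variable genes gave 30 principal components and a graph of 20 neighbours, which leidenalg 0.10.2 split into 40 clusters at resolution 1. No integration between libraries was applied. A cluster took the class whose marker list, fixed in advance, had the most members present in at least 25% of its cells and at least 1 log2 unit above the other clusters, with a minimum of 3 markers and a pseudocount of 10 CPM. Clusters with markers of more than 1 class, and cycling clusters, were split once more, and those that still mixed lineages or had no clear class stayed unnamed. Class names are calls from expression, not from sorting.

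For each library, UMIs were summed per cell class. Genes were tested in 5 main classes with edgeR 4.0.16 (filterByExpr by group, TMM factors, robust quasi-likelihood F-test, two-sided) in R 4.3.3, with all 6 libraries in one fit and 3 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg over all genes tested in that class and comparison, and a gene called changed had an adjusted p under 0.05. The 3 comparisons were Kras against ATTAC, ATTAC_Kras against ATTAC and ATTAC_Kras against Kras. CPM, the UMIs of a gene over those of its class and library, are TMM-scaled except for the levels of Cdkn2a. Shares of cells were tested the same way on cell counts for 28 classes with a mean of at least 10 cells. An exact permutation test of 2 libraries against 2 cannot go below p = 0.333, so none is given for single values. The labels do not say that each library is 1 mouse, so p-values measure the spread between these libraries.

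The 22 gene lists, fixed before the data were examined, were tested with camera in limma 3.58.1 at its preset correlation of 0.01 on log2 CPM with a prior count of 2, wherever at least 5 members were tested. The same test was repeated with the correlation estimated for each list, and with fry, which asks whether the genes of a list move on balance one way. A list was called higher or lower at a camera adjusted p under 0.05 over all lists of that class and comparison, and list members were also adjusted over the list alone.

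Named genes followed in part a rule fixed before the data were examined. Cdkn2a, Cdkn1a and Kras were always named. Up to 12 genes that rose and 12 that fell were taken by size of change among genes past the threshold, with a mean of at least 20 CPM in the higher group and both libraries of one group above both of the other. Genes under 10% of their level in their highest class were marked as possible free RNA. Where fewer than 5 genes passed, the 5 smallest p were named as not passing. Up to 4 members per list that passed over all genes were added. Other named genes were chosen after their values were seen. These include list members that passed only over the list alone and genes called only by an alternative. The 74 genes looked up, those of the rule and some of the others, were all found in the annotation by identifier.

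A share of cells with a UMI carries its 95% Wilson interval, and a count of 0 allows a share of up to 3 counts of the total. Intervals and limits cover counting error only. Shares were also computed after thinning cells to 2000 UMIs, and for Cdkn2a in alveolar macrophages to 10000 UMIs, a depth chosen after seeing the data. Cells below the depth were left out of these shares (2283 of 4822 general capillary cells of library 2 at 2000 UMIs, for example).

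The fit was tested on simulated data with the spread and depth of each class. Of 200 genes set to a 4-fold change, it recovered 87% in alveolar macrophages, 65.5% in interstitial macrophages, 83% in alveolar type 2 cells, 85% in general capillary cells and 88% in T cells. At 2-fold it recovered 43.5%, 2%, 33%, 0% and 39%. With no change set it called 0 to 4 genes. The share test found a 4-fold rise in 1 class in 6 of 50 simulated runs.

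Alternatives were DESeq2 1.42.0, its size factors inside edgeR, no filter on low counts, a fit of only the groups compared, a block for libraries 1 to 3 against 4 to 6, doublets kept, a stricter cell filter (1000 UMIs, 500 genes, 10% mitochondrial), clustering at resolution 2, each library left out in turn, the estimated correlation and fry. Cells of at least 2000 UMIs, and the block in the list test, were added after seeing the data. The block follows the order of the library numbers, which the labels do not name as a batch. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9. Reads were not available, so isoforms of Cdkn2a and the mutant Kras allele were not examined.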

Results

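Single-cell RNA was measured in lungs of C57BL/6 mice at 8 weeks of age, all given AP from birth. The labels name neither AP nor ATTAC further. From background knowledge, AP is a small molecule that dimerises and so activates the caspase of the ATTAC transgene, which in INK-ATTAC mice is driven by the promoter of p16Ink4a, a product of Cdkn2a. Kras marks mice whose lungs are labelled as bearing adenomas, benign tumours that oncogenic Kras starts in the alveolar epithelium. The 3 groups were ATTAC (libraries 1 and 4, healthy lung), Kras (libraries 2 and 5, adenoma) and ATTAC_Kras (libraries 3 and 6, adenoma), with 2 libraries each. If this is the construct used, ATTAC_Kras against Kras contrasts adenoma-bearing lungs with and without a transgene meant to remove p16Ink4a-expressing cells. Whether AP removed any cells was not measured directly. Kras against ATTAC differs in both the adenomas and the transgene.

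The 6 libraries held 43487126 to 98262756 UMIs in 8257 to 16471 barcodes, and the 65218 cells kept had medians of 4210 to 5148 UMIs per library. Clusters were named as endothelial, immune, epithelial and mesenchymal classes, and 1.29 to 6.61% of cells per library stayed unnamed. General capillary cells, the capillary endothelium that also renews the capillaries, were the most abundant class, at 30.7% ± 0.469 (SD, n = 2) of cells in ATTAC, 31.5% ± 0.960 in Kras and 30.7% ± 1.67 in ATTAC_Kras. Alveolar macrophages, the phagocytes of the airspace, made up 8.31% of cells in Kras library 2 and 1.36 to 4.67% in the other 5 libraries. Neutrophils made up 18.2% and classical monocytes 9.89% of cells in ATTAC_Kras library 6, against 3.86 to 7.65% and 0.982 to 3.74% in the other 5. Of the IRESGFP sequence 0 UMIs were counted in any library, the ATTAC libraries included, so it could not serve as a check of the transgene.

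The libraries also differed in part along their numbers, which the labels do not name as a batch. For UMIs summed over all cells the chi-square per degree of freedom over genes was 32.8 between libraries 1 and 3 and 26.7 between 4 and 5, which belong to different groups. Within groups it was 145.1 for libraries 1 and 4, 154.9 for 2 and 5 and 635.2 for 3 and 6. Other pairs went against the numbers, at 267.4 for libraries 4 and 6 and 307.3 for 5 and 6, against 96.0 for 1 and 5 and 105.3 for 3 and 5. Library 6 thus stood apart from libraries 4 and 5 too. These values rise with depth and also reflect the mix of cell classes. Library 6 held 18.2% neutrophils and 9.89% classical monocytes. The Kras gene in general capillary cells stood at 207 to 239 CPM in libraries 1 to 3 and at 114 to 137 CPM in libraries 4 to 6. Counts of genes are therefore also given with a block for libraries 1 to 3 against 4 to 6, called the library order block.

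**Figure D1:**
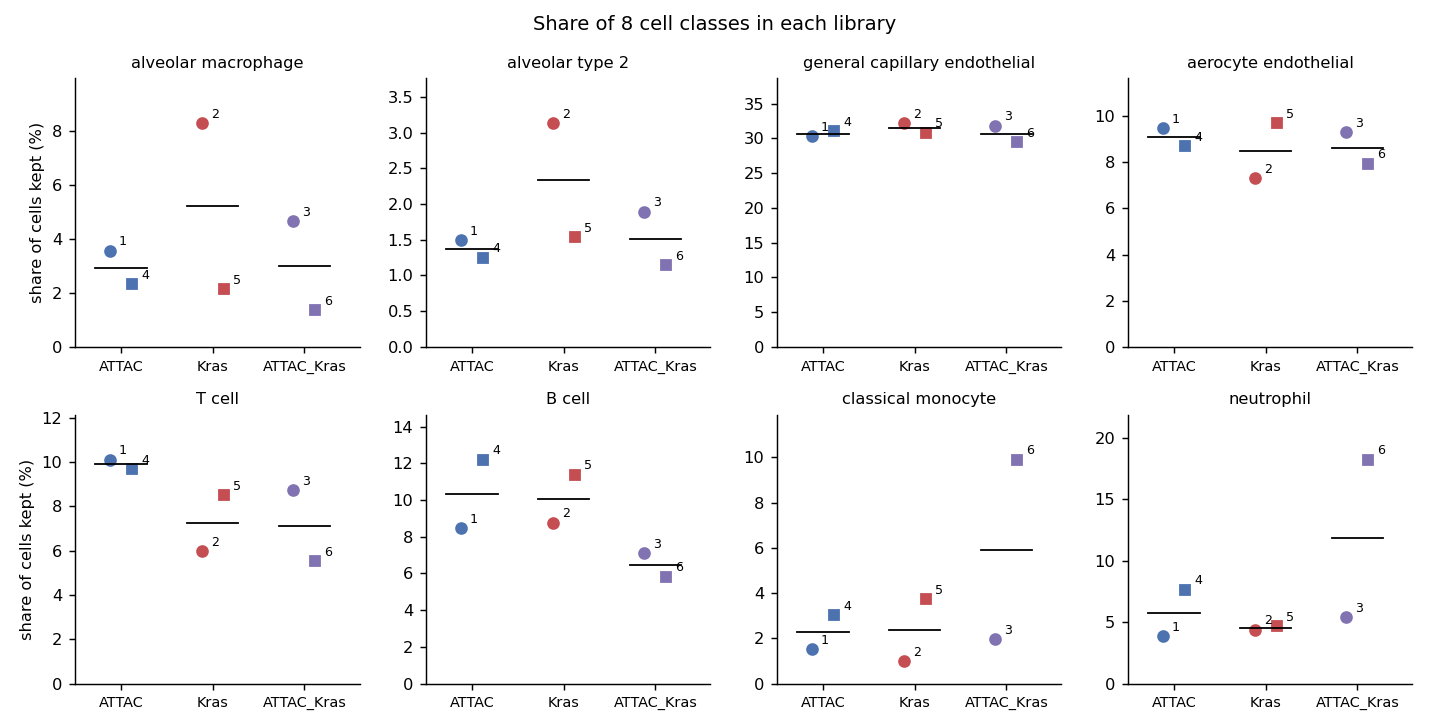
Share of cells kept (%, each axis from 0) in 8 cell classes, 1 panel per class, with the 3 groups on the horizontal axis, dots for libraries 1 to 3, squares for libraries 4 to 6 and a black line at each group mean. Kras library 2 lies highest for alveolar macrophages at 8.31%, and ATTAC_Kras library 6 for neutrophils at 18.2% and classical monocytes at 9.89%.

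Cdkn2a (ENSMUSG00000044303; mm10 chromosome 4, 89274471 to 89294653, minus strand) encodes the cell-cycle inhibitors p16Ink4a and p19Arf, which 3′ counts do not separate. Aerocytes, the capillary endothelium specialised for gas exchange, carried it in every library, at 18.6 and 23.02 CPM in ATTAC, 27.1 and 23.5 in Kras and 32.0 and 11.6 in ATTAC_Kras. They held 57.3, 59.9, 67.8, 57.6 and 45.5% of the Cdkn2a UMIs of named classes in libraries 1, 4, 5, 3 and 6. In Kras library 2 alveolar macrophages held 57.5% and aerocytes 25.04%. There 117 of 1244 alveolar macrophages had a Cdkn2a UMI (9.41%, 95% Wilson interval 7.91 to 11.2%), at 3.00 UMIs per such cell. With cells thinned to 10000 UMIs and shallower ones left out (256 of 1244 in library 2), the share in alveolar macrophages was 76 of 988, or 7.69% (6.19 to 9.52%), in Kras library 2 and 0.676% (0.119 to 3.73%) in Kras library 5. It was 0.535% and 0.565% in ATTAC libraries 1 and 4, and 1.61% and 1.04% in ATTAC_Kras libraries 3 and 6, where the upper bounds reached 3.15% and 5.67%. In general capillary cells of Kras library 2, which should lack the gene, 0.290% had a UMI at a median depth of 2659 UMIs, against a median of 17662 in its alveolar macrophages. The high Cdkn2a level in macrophages was thus measured in 1 of the 2 Kras libraries. Cdkn2a in alveolar macrophages averaged 9.16 ± 10.4 CPM in Kras, 0.608 ± 0.467 in ATTAC and 2.62 ± 3.08 in ATTAC_Kras (SD, n = 2), and no comparison passed without a block (edgeR adjusted p = 1 in all 3). With the library order block Cdkn2a passed in Kras against ATTAC (log2 fold change 4.02, adjusted p = 0.00427, against 0.0663 to 1 under the other alternatives). Library 5 held 6 Cdkn2a UMIs and library 4 held 1, each in 1 alveolar macrophage, and without library 2 the log2 fold change was 1.31. The direction of the other 2 comparisons rested on 1 library each, as ATTAC_Kras against Kras went from -1.62 to 0.930 without library 2 and ATTAC_Kras against ATTAC from 2.28 to -0.628 without library 3. Cdkn2a was too low to be tested in interstitial macrophages and alveolar type 2 cells. In T cells it stood at 3.70 and 3.29 CPM in ATTAC_Kras (28 and 12 UMIs) and 1.15 and 1.21 in Kras (7 and 5 UMIs). ATTAC T cells had 2.59 and 1.74 CPM, and edgeR without a block called 0 genes in T cells. The Kras gene itself (ENSMUSG00000030265) and Cdkn1a (ENSMUSG00000023067), which encodes the cell-cycle inhibitor p21, passed in none of the 15 tests of 5 classes and 3 comparisons. In alveolar type 2 cells, the epithelium that carries surfactant, Kras stood at 121 ± 2.58 CPM in the Kras group and 96.4 ± 11.95 in ATTAC (log2 fold change 0.33, SE 0.160), and the counts do not tell the mutant allele from the normal one.

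**Figure D2:**
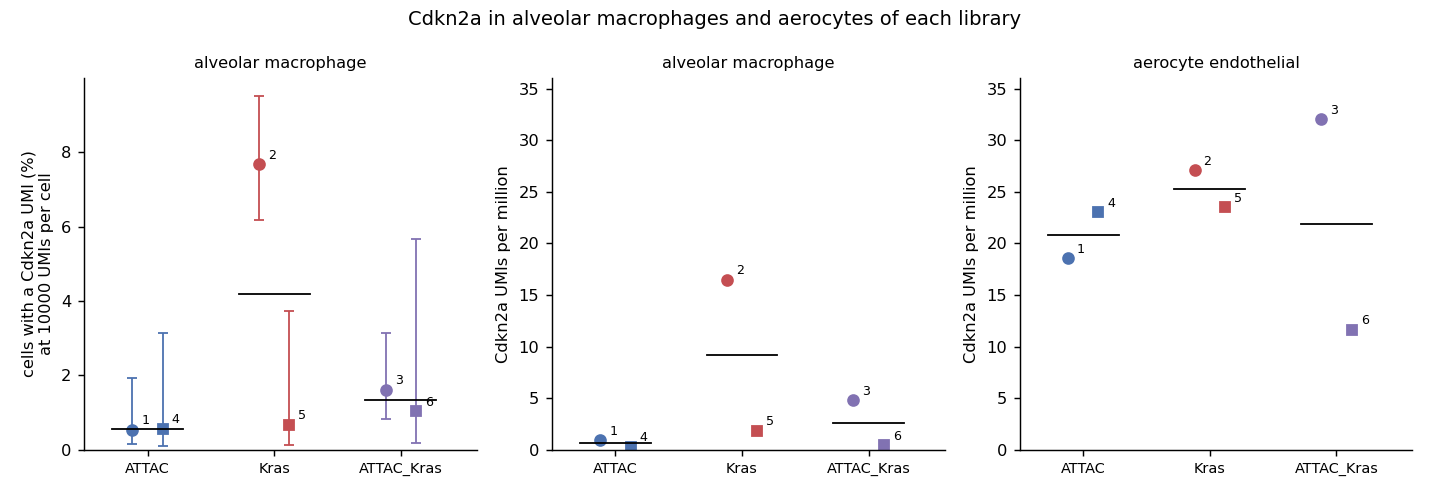
Percent of alveolar macrophages with a Cdkn2a UMI at 10000 UMIs per cell (left, bars are 95% Wilson intervals), and Cdkn2a CPM in alveolar macrophages (middle) and aerocytes (right), with dots for libraries 1 to 3, squares for 4 to 6 and a line at each group mean. Kras library 2 reached 7.69% and 16.5 CPM in alveolar macrophages, and aerocytes carried 11.6 to 32.0 CPM in the 6 libraries.

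In Kras against ATTAC, Cxcl3 and Egr1 stood lower in alveolar macrophages of both Kras libraries. Cxcl3, a neutrophil chemoattractant (ENSMUSG00000029379; chromosome 5, 90786103 to 90789600), stood at 29.9 ± 1.62 CPM in Kras and 106 ± 18.7 in ATTAC (SD, n = 2; log2 fold change -1.84, SE 0.215). Egr1, a transcription factor induced within minutes of stimulation (ENSMUSG00000038418; chromosome 18, 34859823 to 34864984), stood at 229 ± 61.7 against 560 ± 13.9 CPM (-1.30, SE 0.218). Il23a, a cytokine subunit, differed by -3.67 and Ereg, a growth factor of the EGF family, by -1.64. Aig1 differed by 1.10, and 3830403N18Rik stood at 4.99 and 5.80 CPM in Kras and 0 and 0.270 in ATTAC. None of these passed over all 10811 genes without a block (adjusted p = 0.205 for Cxcl3 and 0.584 for Egr1). With the library order block Egr1, Il23a, Aig1 and 3830403N18Rik passed, and Cxcl3 and Ereg did not. DESeq2 called 14 genes, with Cxcl3 (adjusted p = 1.91e-08), Egr1, Il23a, Ereg, Cxcl2, Nfkbia and Il6 lower, and Mmp12, Igf1, Cd63 and Lrg1 among the 7 higher.

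The list of inflammatory and NF-kB genes ranked lower in Kras alveolar macrophages, with 19 of its 22 tested members below ATTAC and a median log2 fold change of -0.38 (camera adjusted p = 6.87e-09; adjusted p = 0.39 with an estimated correlation). The medians were -0.68 for library 2 against 1 and -0.29 for library 5 against 4. Over all genes 0 members passed, and 4 did adjusted over the list alone, all lower. They were Nfkbia, which encodes the inhibitor of NF-kB (-1.22, SE 0.283), Cxcl2 (-1.13, SE 0.257), Il6 (-1.46) and Tnfaip3 (-0.79). The list of stress from tissue dissociation moved with it, with 19 of 22 members lower and a median of -0.30 (camera adjusted p = 7.39e-06; adjusted p = 0.39 with an estimated correlation), and Egr1 and Ier2 passed adjusted over the list alone. Of the KRAS and ERK output list 11 of 16 members were lower, at a median of -0.20 (camera adjusted p = 0.00202; adjusted p = 0.39 with an estimated correlation), at -0.16 for library 2 against 1 and -0.09 for library 5 against 4. Its mean log2 CPM differed mainly in the former pair, at 4.205 against 4.707 and 4.586 against 4.609. Egr1, Ereg and Phlda1 passed adjusted over the list alone. The list of secreted factors of senescent cells was not called (median -0.11, camera adjusted p = 0.0908). Its members went both ways, with Mmp12, a macrophage elastase (2.48, SE 0.592), and Timp2 higher and Cxcl3, Cxcl2, Il6 and Ereg lower, adjusted over the list alone.

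Genes of tumour-associated and repair macrophages ranked higher in Kras, with 17 of 20 members above ATTAC and a median of 0.35 (camera adjusted p = 1.13e-05; adjusted p = 0.39 with an estimated correlation). Igf1, a growth factor (0.97, SE 0.200), Gpnmb, a lysosomal glycoprotein (1.08, SE 0.292), Cxcr2 and Mmp12 passed adjusted over the list alone, and 0 over all genes. The median was 0.59 for library 2 against 1 and -0.003 for library 5 against 4, so it rose in the former pair only. The mean log2 CPM of the list was higher in both, at 7.296 against 6.533 and 6.907 against 6.798. Lipid handling genes had a median of 0.22, with 18 of 25 higher (camera adjusted p = 0.00511; adjusted p = 0.39 with an estimated correlation). The cell-cycle inhibitor and senescence regulator list, which holds Cdkn2a, was not called (camera adjusted p = 0.557).

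In alveolar type 2 cells of Kras lungs, inflammatory genes were lower too. Il6 (ENSMUSG00000025746) stood at 14.8 ± 0.577 CPM against 52.6 ± 17.4 in ATTAC (log2 fold change -1.84, SE 0.282, adjusted p = 0.32), and DESeq2 called it (adjusted p = 0.0375). Nr4a3, an immediate early nuclear receptor, differed by -1.35, Cxcl10 by -1.45 and Plek by -1.29, and Sprr1a had no UMI in either Kras library. The NF-kB list had 18 of 21 members lower (median -0.32, camera adjusted p = 2.65e-06; adjusted p = 0.551 with an estimated correlation), with Il6 and Cxcl10 past adjusted over the list alone. Alveolar macrophage identity genes had a lower mean log2 CPM in these cells too, at 4.366 against 4.679 for library 2 against 1. For library 5 against 4 it was 2.566 against 2.894, so RNA of macrophages was not excluded. The dissociation stress list was lower too (17 of 22 members, median -0.19, camera adjusted p = 0.0419; adjusted p = 0.764 with an estimated correlation), at -0.41 for library 2 against 1 and 0.09 for library 5 against 4. Type I interferon response genes had 18 of 21 members lower, at a median of -0.41 (camera adjusted p = 2.35e-05; adjusted p = 0.551 with an estimated correlation). Neither the surfactant and alveolar type 2 identity list (camera adjusted p = 0.0935) nor the adenoma and transitional epithelium list (median 0.16, camera adjusted p = 0.105) was called.

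Interstitial macrophages gave the 1 gene past the threshold in this comparison. Iigp1, an interferon-inducible GTPase (ENSMUSG00000054072; chromosome 18, 60376027 to 60392634), fell from 155 ± 27.6 to 18.7 ± 6.31 CPM in Kras (log2 fold change -2.91, SE 0.439, adjusted p = 0.047). It rested on 10 UMIs in Kras and 78 in ATTAC, a ratio of 0.128 with a counting interval of 0.0592 to 0.249. Its level in this class was 5.11% of that in general capillary cells, a level marked in advance as possible free RNA. Iigp1 did not pass with DESeq2 (adjusted p = 0.0512), with only the 2 groups compared in the fit (0.163), with the stricter cell filter (0.0559) or at clustering resolution 2 (log2 fold change -1.54, adjusted p = 1). Its adjusted p under the other alternatives ran from 6.31e-06 to 0.0467. Cxcl10, an interferon-induced chemokine, stood at 8.69 and 7.13 CPM in Kras, from 3 UMIs and 1 UMI, and at 229 and 74.0 CPM in ATTAC (adjusted p = 0.0914). Mmp12 differed by 1.87, Plvap by -1.83 and Ly6a by -1.41 (adjusted p = 0.41 each). Plvap and Ly6a reached 6.65% and 4.65% of their levels in endothelial classes. The interferon list had 11 of 13 members lower (median -0.55, camera adjusted p = 0.0328; adjusted p = 0.713 with an estimated correlation).

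In general capillary cells the interferon list had 23 of 26 members lower, at a median of -0.15 (camera adjusted p = 2.31e-05; adjusted p = 0.806 with an estimated correlation), at -0.31 for library 2 against 1 and -0.02 for library 5 against 4. Rab6b, a regulator of vesicle traffic, differed by 2.63 and was called by DESeq2 (adjusted p = 0.000348), as was Sftpb (1.95). Lgals1 differed by 0.80, Gm47015 by -2.21 and Cxcl15 by 1.80 (edgeR adjusted p = 1 each). Sftpb, a surfactant protein gene, belongs to alveolar type 2 cells, and 21 of 23 alveolar type 2 genes were higher in general capillary cells of Kras lungs (median 1.14, camera adjusted p = 1.47e-23; adjusted p = 0.436 with an estimated correlation). The medians were 1.79 for library 2 against 1 and 0.47 for library 5 against 4. Alveolar macrophage identity genes were also highest in library 2 in this class, at a mean log2 CPM of 4.658 against 2.523 to 3.240 in the other libraries. In T cells they stood at 4.100 in library 2 against 2.371 to 2.888, so more free RNA in library 2 is possible. In T cells Ccl4, a chemokine of activated lymphocytes, stood at 50.6 ± 2.90 CPM in Kras and 109 ± 15.1 in ATTAC (log2 fold change -1.12, SE 0.168, adjusted p = 1), and DESeq2 called it (adjusted p = 0.0229). Calca differed by 1.81, Irf8 by 1.11, Spp1 by 1.57 and 4930481A15Rik by 1.62 without passing. The T cell lists of effector and exhaustion genes (camera adjusted p = 0.093) and of naive and memory genes (camera adjusted p = 0.931) were not called. Alveolar type 2 genes had a median of 1.03 in T cells too (18 of 20 higher, camera adjusted p = 3.55e-09; adjusted p = 0.372 with an estimated correlation), at 1.65 for library 2 against 1 and -0.03 for library 5 against 4, and KRAS and ERK output genes one of 0.18 (camera adjusted p = 5.59e-05; adjusted p = 0.286 with an estimated correlation).

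For Kras against ATTAC, edgeR without a block called 0 genes in 4 classes. At unadjusted p under 0.05 lay 262 of 10811 genes in alveolar macrophages and 264 of 11086 in alveolar type 2 cells. In general capillary cells it was 98 of 12994, and in T cells 147 of 11138. Each of these counts lay below 0.05 of the genes tested, the share that chance alone would give. DESeq2 called 14, 1, 2 and 1 in these classes, and edgeR with the library order block called 14, 13, 0 and 9. Genes named above that passed with the block included Mmp12, Egr1, Cxcl2, Nfkbia and Cdkn2a in alveolar macrophages, Il6, Nr4a3, Cxcl10, Plek and Sprr1a in alveolar type 2 cells, and Ccl4, Calca, Irf8, Spp1 and 4930481A15Rik in T cells. Levels under 10% of the highest class, marked in advance as possible free RNA, were those of Egr1, Il23a and Cdkn2a in alveolar macrophages (3.61 to 9.96%), Il6, Nr4a3, Cxcl10 and Plek in alveolar type 2 cells (0.906 to 3.39%), Sftpb, Lgals1 and Cxcl15 in general capillary cells (0.226 to 0.755%) and Ccl4, Irf8 and Spp1 in T cells (0.182 to 0.881%). Without Kras library 5 the alveolar macrophage count was 48, the T cell count 6 and the alveolar type 2 count 2, and without ATTAC_Kras library 3 or 6 the alveolar macrophage count was 1 and the T cell count 2. In interstitial macrophages 178 genes lay under the unadjusted threshold, DESeq2 called Cxcl10 and Thbs1, the block fit called Iigp1 and Cxcl10, and the count was 3 to 30 with any 1 of the 6 libraries left out and 0 with clustering at resolution 2. Thbs1 was named after its values were seen. Of 28 classes 0 changed in share by edgeR, the only tool run on shares, and 1, erythroid cells, with the block. The smallest p was for erythroid cells, at 0.172% ± 0.0962 of cells in Kras and 0.0190% ± 0.0028 in ATTAC (log2 fold change 3.15, adjusted p = 0.261). Alveolar macrophages made up 5.22% ± 4.36 of Kras and 2.95% ± 0.879 of ATTAC cells (adjusted p = 0.964).

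**Figure D3:**
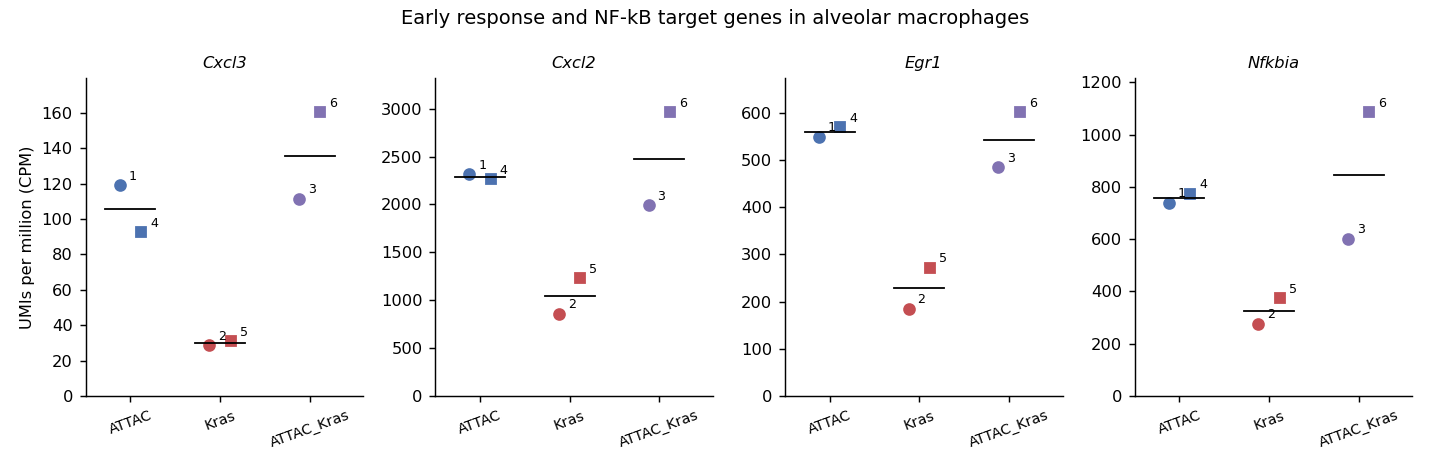
CPM of Cxcl3, Cxcl2, Egr1 and Nfkbia in alveolar macrophages (each axis from 0), with dots for libraries 1 to 3, squares for 4 to 6 and a line at each group mean. Both Kras libraries lie below the 4 others for each gene, for Cxcl3 at 28.7 and 31.0 CPM against 92.7 to 160 CPM.

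In ATTAC_Kras against ATTAC, where both groups carry the transgene and differ in the adenomas, alveolar macrophages had higher tumour and repair genes in both library pairs. The median was 0.42, with 17 of 20 members higher (camera adjusted p = 3.39e-05; adjusted p = 0.845 with an estimated correlation), at 0.29 for library 3 against 1 and 0.26 for library 6 against 4. Lipid handling genes had a median of 0.14 (17 of 25 higher, camera adjusted p = 0.00296; adjusted p = 0.845 with an estimated correlation), and secreted factors of senescent cells one of 0.16 (28 of 41 higher, camera adjusted p = 0.0338; adjusted p = 0.845 with an estimated correlation). The latter list split by library pair, at -0.08 for library 3 against 1 and 0.39 for library 6 against 4. No member of these 3 lists passed over all genes or adjusted over the list alone. F13a1, a transglutaminase of monocytes (log2 fold change -3.15), Pdpn, a membrane glycoprotein (1.46), Cers4, a ceramide synthase (-1.77), Uba52 (-0.81) and Gm19951 (1.14) had the smallest p, each with an adjusted p of 1.

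Interstitial macrophages of ATTAC_Kras lungs had lipid handling and alveolar macrophage genes that ranked higher than in ATTAC, with no gene past the threshold without a block. Ccl6, a macrophage chemokine (ENSMUSG00000018927; chromosome 11, 83587882 to 83593087), stood at 2800 ± 851 against 792 ± 26.9 CPM (log2 fold change 1.82, SE 0.300, adjusted p = 0.0607). Msrb1, which repairs oxidised methionine (2.23), Ednrb, an endothelin receptor (153 ± 46.7 against 10.2 ± 8.89 CPM), and Ear2, a ribonuclease of alveolar macrophages (2.46), were higher, and Lyve1, a hyaluronan receptor of perivascular macrophages (-2.93), was lower, with adjusted p from 0.0607 to 0.0609. Msrb1, Ednrb, Ear2 and Lyve1 lay at 4.52 to 7.82% of the level in their highest class, so free RNA is possible for these 4. Another chemokine, Ccl5, named after its values were seen, was lower (60.6 ± 43.1 against 459 ± 219 CPM, log2 fold change -2.985, SE 0.516, adjusted p = 0.072), and it passed adjusted over the list alone in the 3 lists that hold it. Its level in this class was 1.05% of that in natural killer cells. With the library order block Ccl6, Msrb1, Ednrb and Lyve1 were among 7 genes that passed. DESeq2 called 11 genes, and 266 lay under an unadjusted p of 0.05. Lipid handling genes had a median of 0.64, with 16 of 20 higher (camera adjusted p = 0.00129; adjusted p = 0.447 with an estimated correlation), and Abcg1, a cholesterol exporter (1.31), and Idi1, of cholesterol synthesis, which had 1 UMI in each ATTAC library, passed adjusted over the list alone. Hypoxia and glycolysis genes had a median of 0.71 (9 of 11 higher, camera adjusted p = 0.00377; adjusted p = 0.429 with an estimated correlation), at 0.23 for library 3 against 1 and 1.03 for library 6 against 4. Alveolar macrophage identity genes had a median of 0.60 in this class (14 of 18 higher, camera adjusted p = 0.00279; adjusted p = 0.37 with an estimated correlation), in the same libraries as the other lists.

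In alveolar type 2 cells the adenoma and transitional epithelium list was higher in both pairs, with 18 of 22 members up and a median of 0.45 (camera adjusted p = 5.12e-05; adjusted p = 0.769 with an estimated correlation), at 0.58 for library 3 against 1 and 0.30 for library 6 against 4. Lypd2, a secretory-cell gene, stood at 21.1 ± 11.1 CPM in ATTAC_Kras and 2.21 ± 0.346 in ATTAC (log2 fold change 3.33, SE 0.480, adjusted p = 0.274), and DESeq2 called it (adjusted p = 0.0292). Lypd2 reached only 5.21% of its level in ciliated cells. Il6 differed by -1.50, Plek by -1.22 and Il23a by -3.20 without passing, and Cxcl5 was seen only in the ATTAC_Kras libraries, at 4.87 and 7.55 CPM. MHC class I genes had a median of 0.34 (12 of 14 higher, camera adjusted p = 0.00115; adjusted p = 0.769 with an estimated correlation), at 0.004 for library 3 against 1 and 0.75 for library 6 against 4. Matrix and TGF-beta response genes had a median of -0.41 (13 of 19 lower, camera adjusted p = 0.0149; adjusted p = 0.769 with an estimated correlation), but the pairs went opposite ways, at 0.13 for library 3 against 1 and -0.82 for library 6 against 4. The surfactant and alveolar type 2 identity list was not called (camera adjusted p = 0.879).

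General capillary cells had higher interferon and antigen presentation genes, mainly in library 6. The interferon list had 23 of 26 members higher and a median of 0.45 (camera adjusted p = 2.58e-12; adjusted p = 0.602 with an estimated correlation), at 0.14 for library 3 against 1 and 0.66 for library 6 against 4. All 14 MHC class I genes were higher, at a median of 0.58 (camera adjusted p = 0.000108; adjusted p = 0.602 with an estimated correlation), but the median was -0.005 for library 3 against 1 and 0.96 for library 6 against 4. MHC class II genes had a median of 0.76 (camera adjusted p = 0.0189; adjusted p = 0.602 with an estimated correlation), at 0.01 for library 3 against 1 and 1.17 for library 6 against 4. Rab6b differed by 1.97 (SE 0.517), Sema4a by 1.00, Ip6k3 by 1.32, Sulf1, an enzyme that edits heparan sulfate, by -0.64 and Gxylt2 by -0.94, each with an adjusted p of 1. In T cells Ccl4 stood at 47.7 ± 4.61 CPM against 109 ± 15.1 (log2 fold change -1.20, SE 0.169, adjusted p = 0.823), and DESeq2 called Ccl4 (adjusted p = 0.00337) and Calca (2.07, adjusted p = 0.0429). Slc7a8, an amino acid transporter, differed by 2.22 and 5830468F06Rik by 1.07 (adjusted p = 1), and Fut10 had no UMI in either ATTAC_Kras library.

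For ATTAC_Kras against ATTAC, edgeR without a block called 0 genes in any of the 5 classes. At unadjusted p under 0.05 lay 150 genes in alveolar macrophages, 266 in interstitial macrophages, 199 in alveolar type 2 cells, 118 in general capillary cells and 178 in T cells, and DESeq2 called 0, 11, 1, 0 and 2. Of the unadjusted counts only that of interstitial macrophages, with 4635 genes tested, lay above the share of 0.05 that chance alone would give. With the library order block edgeR called 0, 7, 6, 0 and 3, among them Lypd2 and Il6 in alveolar type 2 cells and Ccl4 and Calca in T cells. Levels under 10% of the highest class were those of F13a1, Pdpn and Cers4 in alveolar macrophages (0.808 to 3.66%), Lypd2, Il6, Plek, Cxcl5 and Il23a in alveolar type 2 cells (0.906 to 7.05%), Sulf1, Gxylt2 and Sema4a in general capillary cells (1.99 to 7.12%) and Ccl4 and Slc7a8 in T cells (0.343 and 1.47%). The interstitial macrophage count was 6 to 45 with a library left out, the alveolar type 2 count 6 without library 3 and 9 without library 6, and the T cell count 1 without library 3. Of 28 classes 0 changed in share by edgeR, with the smallest p for pericytes, the cells that wrap capillaries, at 1.60% ± 0.053 in ATTAC_Kras and 2.69% ± 0.0714 in ATTAC (log2 fold change -0.75, adjusted p = 0.733). Neutrophils made up 11.8% ± 9.05 of ATTAC_Kras and 5.75% ± 2.68 of ATTAC cells (adjusted p = 0.733).

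In ATTAC_Kras against Kras, 4 genes changed in interstitial macrophages, 3 of them chemokines. Cxcl13, a B cell attractant (ENSMUSG00000023078; chromosome 5, 95956951 to 95961068), fell from 640 ± 184 CPM in Kras to 69.2 ± 45.2 in ATTAC_Kras (SD, n = 2; log2 fold change -3.13, SE 0.406, adjusted p = 0.00876). Cxcl10, which attracts activated T cells (ENSMUSG00000034855; chromosome 5, 92346638 to 92348889), rose from 7.91 ± 1.11 to 275 ± 25.4 CPM (adjusted p = 0.00876). The Kras libraries held 3 and 1 Cxcl10 UMIs, which gave a ratio of 34.6 with a counting interval of 13.3 to 128. Ccl6 rose from 737 ± 216 to 2800 ± 851 CPM (1.92, SE 0.302, adjusted p = 0.0251). It was also seen in 100% of alveolar macrophages of at least 10000 UMIs in Kras library 2. Alveolar macrophage identity genes had a higher mean log2 CPM in interstitial macrophages of both pairs. They stood at 7.438 in library 3 against 7.111 in 2, and at 6.950 in library 6 against 6.366 in 5. RNA of alveolar macrophages was thus not excluded for Ccl6. Iigp1 rose from 18.7 ± 6.31 to 124 ± 0.812 CPM (2.58, SE 0.443, adjusted p = 0.0462), again at 5.11% of its general capillary level.

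All 4 genes moved in the same direction in library 3 against 2 and in library 6 against 5. The naming rule required both libraries of one group above both of the other, so this agreement is no independent support. The class held 30 to 102 cells per library, with median depths from 1431 UMIs in library 2 to 5858 in library 1. At clustering resolution 2, where 8282 genes were tested, 0 genes passed and the log2 fold changes were -2.81 for Cxcl13, 1.36 for Cxcl10, 1.32 for Ccl6 and 2.62 for Iigp1. DESeq2 called Cxcl13, Cxcl10 and Ccl6, and without library 2 Cxcl10 (adjusted p = 0.107) and Iigp1 (adjusted p = 0.0819) no longer passed. Ear2 differed by 2.54 (adjusted p = 0.0528), at 7.82% of its level in alveolar macrophages, and changed sign at clustering resolution 2. The interferon list had 12 of 13 members higher, at a median of 0.92 (camera adjusted p = 7.61e-05; adjusted p = 0.536 with an estimated correlation), and Irf7 and Ifi47 passed adjusted over the list alone. All 13 tested MHC class I genes were higher, at a median of 0.60 (camera adjusted p = 1.38e-06; adjusted p = 0.536 with an estimated correlation).

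**Figure D4:**
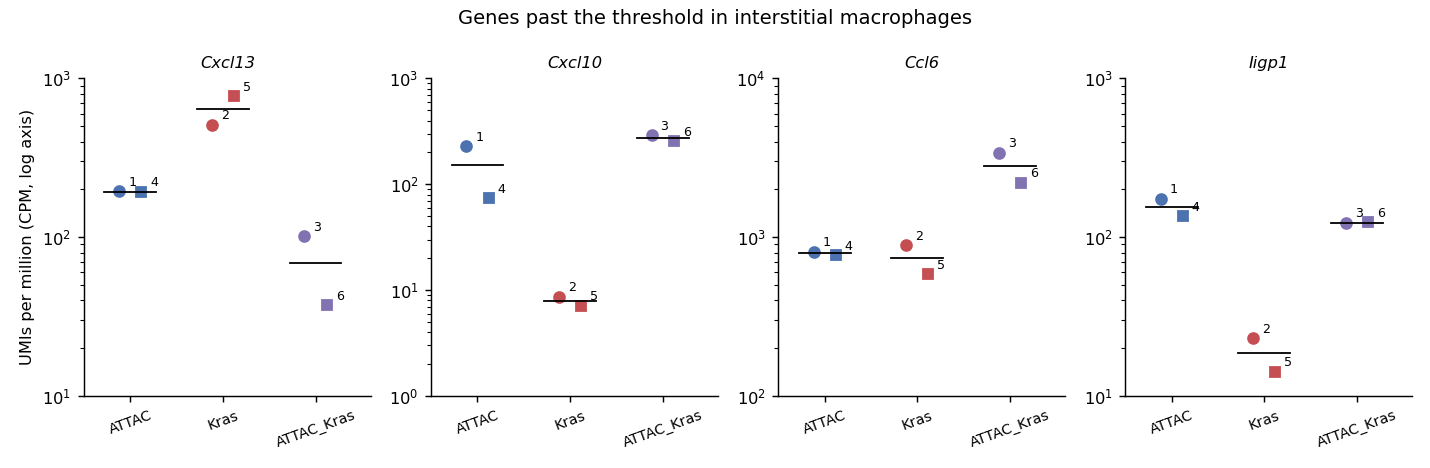
CPM of Cxcl13, Cxcl10, Ccl6 and Iigp1 in interstitial macrophages (log axes), with dots for libraries 1 to 3, squares for 4 to 6 and a line at each group mean. Both Kras libraries lie above both ATTAC_Kras libraries for Cxcl13 (510 and 770 against 101 and 37.3 CPM) and below them for the other 3 genes.

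Alveolar macrophages of ATTAC_Kras lungs carried more of the early response and NF-kB genes than those of Kras lungs. Cxcl3 stood at 136 ± 34.4 against 29.9 ± 1.62 CPM (log2 fold change 2.18, SE 0.217, adjusted p = 0.0594), Egr1 at 543 ± 82.2 against 229 ± 61.7 CPM (1.25, SE 0.218, adjusted p = 1), Il23a differed by 3.70, Ereg by 1.70 and Cers4 by -2.13. DESeq2 called 7 genes, with Cxcl3 (adjusted p = 5.29e-13), Egr1, Il23a, Cxcl2, Nfkbia and Ereg higher and F10, a coagulation factor, lower. The NF-kB list had 19 of 22 members higher, at a median of 0.68 (camera adjusted p = 3.46e-14; adjusted p = 0.355 with an estimated correlation), with medians of 0.51 for library 3 against 2 and 0.86 for library 6 against 5. Adjusted over the list alone 6 members were higher, Nfkbia (1.37), Cxcl2 (1.24), Tnf (2.19), Nfkbiz (1.59), Tnfaip3 and Irf1, and over all genes 0. The dissociation stress list moved with it (19 of 22 higher, median 0.35, camera adjusted p = 5.06e-09; adjusted p = 0.249 with an estimated correlation). Its mean log2 CPM was higher in ATTAC_Kras in both pairs in T cells too (7.224 against 7.053 and 7.041 against 6.715). The same held in interstitial macrophages (9.732 against 9.672 and 9.822 against 9.565) and, as given below, in general capillary and alveolar type 2 cells. Whether handling caused this rise was not tested. Secreted factors of senescent cells had a median of 0.13 (camera adjusted p = 6.5e-05; adjusted p = 0.355 with an estimated correlation), with 24 of 41 members higher and Cxcl3, Cxcl2 and Ereg past adjusted over the list alone. KRAS and ERK output genes had a median of 0.26 (camera adjusted p = 0.000889; adjusted p = 0.355 with an estimated correlation). The tumour and repair list split by library pair, at -0.50 for library 3 against 2 and 0.24 for library 6 against 5. Type I interferon genes had a lower mean log2 CPM in ATTAC_Kras in both pairs, at 3.249 against 3.381 and 3.209 against 3.512. Of that list Ifi27l2a (-1.05) passed adjusted over the list alone.

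General capillary cells of ATTAC_Kras lungs had more interferon-response RNA. All 26 tested members were higher than in Kras, at a median of 0.53 (camera adjusted p = 2.08e-22; adjusted p = 0.466 with an estimated correlation), with medians of 0.41 for library 3 against 2 and 0.63 for library 6 against 5. Ifit1, an antiviral RNA-binding protein, stood at 519 ± 5.21 against 224 ± 17.3 CPM (log2 fold change 1.21, SE 0.247), and Ifit1, Ifit3, Ifi44 and Ifi204 passed adjusted over the list alone. DESeq2 called Ifit1 (adjusted p = 0.0279), Ifit3 and Gbp5 higher and Sftpb and Cxcl15 lower. All 14 MHC class I genes were higher, at a median of 0.66 (camera adjusted p = 4.41e-06; adjusted p = 0.517 with an estimated correlation), with 0.13 for library 3 against 2 and 0.95 for library 6 against 5. Gbp5 differed by 1.92, Sulf1 by -0.85, Cbr2 by -1.07 and Sftpb by -1.82 (edgeR adjusted p = 1 each). All 23 alveolar type 2 genes were lower in this class (median -1.26, camera adjusted p = 1.05e-15; adjusted p = 0.466 with an estimated correlation). The dissociation stress list had a higher mean log2 CPM in general capillary cells too. It stood at 10.265 in library 3 against 10.082 in 2, and at 10.104 in library 6 against 9.448 in 5.

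**Figure D5:**
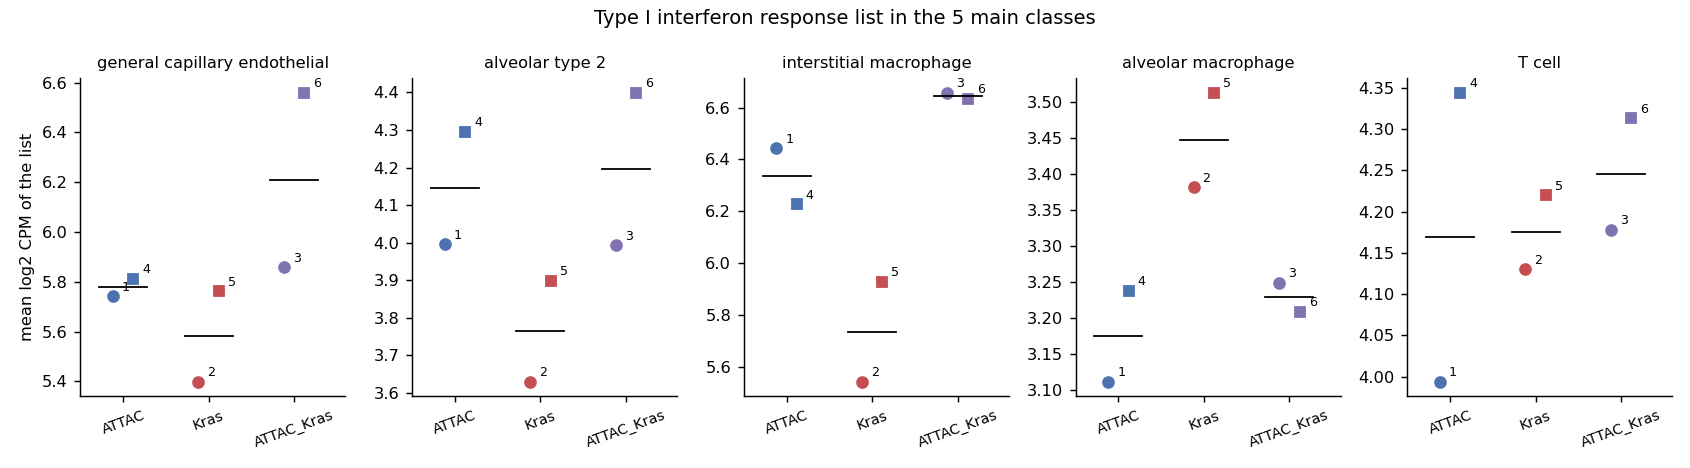
Mean log2 CPM over the tested members of the type I interferon response list in the 5 main classes, 1 panel per class with its own axis, dots for libraries 1 to 3, squares for 4 to 6 and a line at each group mean. In general capillary cells both ATTAC_Kras libraries lie above both Kras libraries, where all 26 members had a positive fold change at a median of 0.53.

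In alveolar type 2 cells the interferon list had 17 of 21 members higher in ATTAC_Kras than in Kras (median 0.56, camera adjusted p = 4.6e-06; adjusted p = 0.609 with an estimated correlation), at 0.33 for library 3 against 2 and 0.56 for library 6 against 5. All 21 tested NF-kB genes were higher, at a median of 0.33 (camera adjusted p = 2.05e-05; adjusted p = 0.609 with an estimated correlation). The dissociation stress list moved with them (19 of 22 higher, median 0.17, camera adjusted p = 0.000268; adjusted p = 0.609 with an estimated correlation), at 0.33 for library 3 against 2 and -0.01 for library 6 against 5. Its mean log2 CPM was higher in both pairs, at 9.233 against 8.850 and 8.881 against 8.546. Alveolar macrophage identity genes stood at 4.720 against 4.366 and 2.608 against 2.566 in the same cells, a rise mainly in library 3 against 2. Scgb1a1, the secretoglobin of club cells, stood at 25390 ± 8232 against 5893 ± 113 CPM (log2 fold change 2.11, SE 0.351, adjusted p = 0.691), and DESeq2 called it (adjusted p = 9.53e-09). It belongs to the fixed list of free RNA candidates from other cell types, where it passed adjusted over the list alone (edgeR adjusted p = 0.00389). No club cell class was named, so its level there was not measured and free RNA is possible. Gsto1 differed by 2.34, Lypd2 by 2.36, Nr4a3 by 1.15 and Tnip3, an inhibitor of NF-kB signalling, by 2.97 without passing. In T cells neither the interferon list (median 0.10, camera adjusted p = 0.0743) nor the effector and exhaustion list (camera adjusted p = 0.0887) was called. Ebf1, a B cell factor, differed by -1.60, Fmo2 by -0.93 and Mrm3 by 1.11 (adjusted p = 1), and Penk stood at 3.04 and 9.72 CPM in Kras and 0 and 0.300 in ATTAC_Kras.

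For ATTAC_Kras against Kras, edgeR without a block called 0 genes outside interstitial macrophages. At unadjusted p under 0.05 lay 164 genes in alveolar macrophages, 207 in alveolar type 2 cells, 214 in general capillary cells and 166 in T cells, and DESeq2 called 7, 1, 5 and 0. Each of the unadjusted counts lay below 0.05 of the genes tested in its class, the share that chance alone would give. With the library order block edgeR called 8, 6, 0 and 1, among them Cxcl3, Egr1, Il23a, Cxcl2, Nfkbia and F10 in alveolar macrophages, Gsto1, Lypd2 and Scgb1a1 in alveolar type 2 cells and Penk in T cells. Levels under 10% of the highest class were those of Il23a, Egr1 and Cers4 in alveolar macrophages (3.61 to 5.77%), Gsto1, Lypd2, Nr4a3 and Tnip3 in alveolar type 2 cells (0.345 to 5.21%), Sulf1, Cbr2 and Sftpb in general capillary cells (0.149 to 3.53%) and Penk, Ebf1 and Fmo2 in T cells (0.237 to 1.87%). In interstitial macrophages it called 8, which included the 4 genes above and Ear2. With a library left out, the interstitial macrophage count was 10 to 35. The alveolar type 2 count was 10 without library 3 and 6 without library 6, the T cell count 4 without library 5, 2 without library 3 and 1 without library 6, and the alveolar macrophage count 1 without library 1, 4, 5 or 6. Of 28 classes 0 changed in share by edgeR. Neutrophils made up 11.8% ± 9.05 of ATTAC_Kras and 4.53% ± 0.214 of Kras cells (log2 fold change 1.38, adjusted p = 0.652).

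Iigp1 in interstitial macrophages was the 1 gene that edgeR without a block called in both Kras against ATTAC, where it fell, and ATTAC_Kras against Kras, where it rose. DESeq2 called it in neither. Both comparisons use the Kras libraries, so chance alone gives opposite signs, and in 10 simulations with no change the number of such genes in this class averaged 0.7 and reached 2. Lists called by camera numbered 33 of 106 class and list pairs in Kras against ATTAC (24 higher), 35 in ATTAC_Kras against ATTAC (27 higher) and 38 in ATTAC_Kras against Kras (22 higher). With an estimated correlation 0 were called, at smallest adjusted p of 0.286, 0.37 and 0.249, and by fry 0, at 0.532, 0.345 and 0.46. Without Kras library 2 the first count was 19, and without ATTAC_Kras library 6 the second was 19.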

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

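The tests of dissociation stress, of the adenomas by themselves, of library 6 and of free RNA in general capillary cells were chosen after the results were seen, and that of neutrophil RNA before.

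KRAS and ERK output genes moved apart between classes in Kras against ATTAC, with a median log2 fold change of 0.180 in T cells, where both library pairs were positive, and -0.204 in alveolar macrophages, where both were negative. Type I interferon genes had a median of 0.153 in alveolar macrophages against -0.405 in alveolar type 2 cells and -0.554 in interstitial macrophages, each in both library pairs. Neither difference between classes was tested.

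The lower NF-kB and early response genes of Kras alveolar macrophages could come from handling, from other cells' RNA or from the macrophages' own state. Stress of dissociation acting on all cells alike would lower the same genes in every class, but in 3 of the 4 other main classes the median of the members was near or above 0, against -0.352 in alveolar macrophages, at 0.037 in interstitial macrophages, -0.041 in general capillary cells and 0.118 in T cells. Alveolar type 2 cells reached -0.242, so a stress response that differs by cell type stays open. Set against ATTAC_Kras, the dissociation stress list had a lower mean log2 CPM in Kras in both library pairs in all 5 main classes. In general capillary cells it was 10.082 in library 2 against 10.265 in 3, and 9.448 in library 5 against 10.104 in 6. Stress shared by all classes thus stays open for that comparison. Neutrophil RNA would have to fall with the listed genes, but S100a8 and S100a9 were higher in Kras alveolar macrophages in both pairs, by mean log2 ratios of 0.537 and 0.397. Adenomas by themselves would lower the genes in ATTAC_Kras lungs alike. The lower quartile of the members' log2 ratio of ATTAC_Kras over Kras was above 0 in both pairs. It was 0.228 for library 3 against 2 and 0.226 for library 6 against 5. These ratios reuse the Kras libraries in which the low values were seen, so chance alone favours ratios above 0. Against ATTAC, the NF-kB list had a mean log2 CPM of 6.262 in library 3 and 6.477 in library 1. It stood at 6.863 in library 6 and 6.628 in library 4, so the pairs went opposite ways and the test does not decide. The adenomas, the absence of ATTAC, or both, and the tumour burden of each lung stay open as undecided or untested biological explanations.

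The higher interferon genes in general capillary cells of ATTAC_Kras than of Kras were also seen without library 6, in library 3 against 2. The lower quartile of the members there was 0.245 above Kras, with a median of 0.406. Library 2 had the lowest mean log2 CPM of the list, at 5.399, and library 3 stood at 5.858. Kras library 5 stood at 5.763 and ATTAC libraries 1 and 4 at 5.743 and 5.812. The rise in library 3 thus rested largely on the low value of library 2. Free RNA shared by all droplets would add as many UMIs to T cells as to general capillary cells. The rise in UMIs per 1000 cells was larger in general capillary cells for 21 of 25 members in library 3 against 2 and for 24 in library 6 against 5, and the lower quartile of the difference was above 0 in both, at 6.78 and 41.04. This argues against free RNA as the whole cause, and a smaller part stays open. An interferon response that differs between these libraries for reasons other than the transgene may account for it too and was not tested.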

How the results depend on the processing

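The counts of cells of at least 2000 UMIs, and the library order block in the list test, were chosen after the results were seen, and all other alternatives before. The labels pair no libraries across groups. The library order block, which sets 1 library of each group in each block, comes nearest to a paired fit and follows the library numbers only. Counts follow the order Kras against ATTAC, ATTAC_Kras against ATTAC, ATTAC_Kras against Kras, and only those that moved by over 1.5 times are given. No result changed direction between the main and an alternative setting where it passed the threshold in either. The cause of the moves was not tested unless stated.

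With DESeq2 the alveolar macrophage counts were 14 in the first and 7 in the third comparison, the interstitial macrophage counts 2 and 11 in the first and second, the alveolar type 2 counts 1, 1 and 1, the general capillary counts 2 in the first and 5 in the third, and the T cell counts 1 and 2 in the first and second. With no filter on low counts they were 65, 26 and 34 in alveolar macrophages, 28, 71 and 39 in interstitial macrophages, 40, 19 and 40 in alveolar type 2 cells, 7, 1 and 13 in general capillary cells, and 17, 5 and 12 in T cells. With only the 2 groups compared in the fit the first comparison gave 1 in alveolar macrophages and 2 in T cells, and interstitial macrophages gave 0, 26 and 15. With the library order block alveolar macrophages gave 14 and 8 in the first and the third, interstitial macrophages 2, 7 and 8, alveolar type 2 cells 13, 6 and 6, T cells 9, 3 and 1, and shares 1 class (erythroid cells, Kras against ATTAC). Interstitial macrophages gave 0 in the first comparison with the stricter cell filter, 0, 1 and 0 at clustering resolution 2, and 4, 9 and 7 with cells of at least 2000 UMIs. Lists called fell from 33, 35 and 38 to 0, 0 and 0 with the correlation estimated and to 0, 0 and 0 by fry, and were 37, 40 and 39 with the block.

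With each library left out in turn, where the lone library of a group is assumed to vary like the others, the counts ran from 0 to 48, 0 to 0 and 0 to 1 in alveolar macrophages, 3 to 30, 6 to 45 and 10 to 35 in interstitial macrophages, 0 to 2, 0 to 9 and 0 to 10 in alveolar type 2 cells, 0 to 0 in general capillary cells, and 0 to 6, 0 to 1 and 0 to 4 in T cells. Lists ran from 19 to 49, 19 to 39 and 27 to 48, and classes changed in share stayed at 0. The 48 came without Kras library 5, and the list counts of 19 without Kras library 2 and ATTAC_Kras library 6.

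Of 1686 values of named genes under alternatives 1472 kept their side of the threshold, 170 passed that had not, 11 no longer passed and 33 changed sign without passing. Those included Cdkn2a in alveolar macrophages, at 0.930 without library 2 (ATTAC_Kras against Kras) and -0.628 without library 3 (ATTAC_Kras against ATTAC), and Ear2 in interstitial macrophages at resolution 2. Of 1072 class shares 967 stayed and 104 changed sign or reached 0 without passing. Among them were alveolar macrophages in both comparisons with Kras without library 2 and neutrophils in ATTAC_Kras against ATTAC without library 6. Of 44 shares of cells with a UMI 31 moved when cells were thinned to 2000 UMIs and shallower cells left out. Having 2 libraries per group limits the precision. Simulated 2-fold changes were recovered at 2% in interstitial macrophages, with 30 to 102 cells per library, and at 0% in general capillary cells, with 2368 to 4822, so cell number alone did not set the recovery.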

Other observations

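The tests of Cdkn2a in Kras library 2, the depth of 10000 UMIs behind them and the genes of its Cdkn2a-positive cells were chosen after the results were seen, and the other splits of the libraries before.

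Within Kras library 2, alveolar macrophages with a Cdkn2a UMI differed in other genes from those without, among cells of at least 10000 UMIs (103 against 885 cells, 1 library, so no test between samples was possible). Cells were sorted by Cdkn2a before thinning, and the other genes were counted after these cells were thinned to 10000 UMIs. Trem2, a lipid receptor of tumour-associated macrophages, was seen in 57.3% against 33.3% of cells, Igf1 in 75.7% against 60.7%, Gdf15, a stress cytokine, in 54.4% against 38.9%, and Gpnmb in 93.2% against 81.8%. Spp1, of the same tumour and repair list as Trem2, Igf1 and Gpnmb, went the other way, in 68.9% against 82.3%. Cidec, a lipid droplet protein, was seen in 19.4% against 61.9%, Krt79 in 37.9% against 74.4%, and Marco, a scavenger receptor, in 31.1% against 51.6%. Cxcl2 was seen in 39.8% against 60.3%, and Cdkn1a in 60.2% against 73.2%. These genes were picked after their values were seen. Among cycling alveolar macrophages of ATTAC lungs a Cdkn2a UMI was seen in 8 of 40 cells in library 1 and 4 of 21 in library 4. In Kras 23 of 104 and 1 of 12 cells had one, and in ATTAC_Kras 17 of 57 in library 3 and 0 of 10 in library 6, which allows a share of up to 30%. Their median depths were 16325 to 27179 UMIs per library. Other alveolar macrophages of libraries 1 and 4 had a UMI in 0.976% (upper bound 2.48%) and 0.444% (upper bound 2.47%) of cells. Their median depths were 18404 and 17719 UMIs. In alveolar type 2 cells of the same libraries, at median depths of 21875 and 16347 UMIs, the share reached at most 1.16%. These shares argue against free RNA shared by all droplets as the whole source in the cycling cells of libraries 1 and 4. At 2000 UMIs 0 of 40 and 0 of 21 of those cycling cells had a UMI, which allows shares of up to 7.50% and 14.3%, so that depth did not decide.

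Other gene groups moved in general capillary cells of ATTAC_Kras lungs. Unfolded protein and oxidative stress genes had a median log2 fold change of 0.16 against Kras (camera adjusted p = 0.000938; adjusted p = 0.517 with an estimated correlation), with a mean log2 CPM lower in library 3 than in 2 (5.962 against 6.021) and higher in library 6 than in 5 (5.849 against 5.410), and cell-cycle inhibitors and senescence regulators one of 0.10 (camera adjusted p = 0.00954; adjusted p = 0.466 with an estimated correlation). Endothelial activation genes had a median of -0.17 (camera adjusted p = 0.00954; adjusted p = 0.466 with an estimated correlation), and matrix and TGF-beta genes one of -0.13 (camera adjusted p = 0.00943; adjusted p = 0.466 with an estimated correlation). In T cells MHC class II genes had a median of -0.23 against Kras, with 9 of 10 members lower (camera adjusted p = 0.00997; adjusted p = 0.554 with an estimated correlation), at -0.36 for library 3 against 2 and -0.10 for library 6 against 5. The B cell factor Ebf1 was lower in the same cells (-1.60), so RNA of B cells was not excluded. Sftpc, the most abundant alveolar type 2 transcript, stood at 958 and 302 CPM in general capillary cells of Kras libraries 2 and 5, and at 120 to 230 CPM in the other 4 libraries.

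The Cdkn2a-carrying alveolar macrophages of Kras library 2 could be an effect of free RNA, of depth or of genotype. A candidate explanation is a macrophage state present in the lung tissue of that library. Against free RNA, the upper bound of the share of general capillary cells with a UMI in that library, at 2000 UMIs per cell, was 0.404%, below the lower bound of 1.25% in its alveolar macrophages. Against depth, the median of 17662 UMIs per alveolar macrophage in library 2 lay within the 17457 to 20800 of the others, and the lower bound of 6.19% at 10000 UMIs lay above the upper bounds of the other 5 libraries, the highest of which was 5.67%. At 2000 UMIs, where 21 of 1105 cells had a UMI, the lower bound of 1.25% lay above the upper bound of library 1 (0.970%) and below those of the other 4 (1.64 to 3.54%). The Kras genotype by itself cannot be told apart from differences between libraries. Both Kras libraries, unlike all the others, also lack ATTAC by their labels. If ATTAC removed Cdkn2a-expressing cells, the low shares in the ATTAC and ATTAC_Kras libraries would not be a normal baseline. This was not tested. The upper bound of 3.73% in Kras library 5 at 10000 UMIs only restates that the Kras libraries differ, and at 2000 UMIs its upper bound of 3.54% lay above the lower bound in library 2. Tumour burden and the mouse or mice behind library 2 were not measured and stay open.

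The 6 libraries can be split into 3 pairs in 15 ways, too few for a share under 0.05. Over the 5 classes and 3 comparisons the real split gave 5 genes past the threshold, and 11 of the 15 splits gave as many, with up to 145 for the pairs 1 with 6, 2 with 3 and 4 with 5. That split calls many times the real count, which points to a structure of the samples along library order, since the 6 splits that pair one of libraries 1 to 3 with one of 4 to 6 gave 1 to 8 genes. For lists the real split gave 106 calls, 1 of the 15 splits gave as many, and the highest of the others gave 105.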
